A study of Mus musculus with 2 samples.

How the data were processed

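Gene expression was measured on 2 Affymetrix expression arrays of mouse peritoneal macrophages. Per the labels, the cells came from male C57BL/6 mice and had been transfected 48 h earlier with a control siRNA (1 array) or with an siRNA against HDAC9 (1 array). Total RNA was extracted, its integrity was inspected on a Bioanalyzer and biotin-labelled cRNA was made, per the labels' protocols; the RNA integrity values themselves are not given in the sources used here. The labels do not say whether RNA from several mice was pooled.

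The deposited values are log2 signals per probe set, 1 column per array. MAS5, an Affymetrix algorithm that condenses the probes of each set into 1 signal, is named in the submitters' processing notes; its version and settings, its scaling target and its detection calls are not given in the sources used here. The deposited table held 45037 probe sets, with values from 0 to 15.2. After undoing the log2, the mean signal without the highest and lowest 2% of probe sets was 497 on both arrays, close to a common scaling target of 500, so the authors' scaling was kept. A value of exactly 0 was listed for 170 probe sets on the control array and 139 on the HDAC9 siRNA array.

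Probe sets were named from a platform annotation of 2016, with symbols checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6. Of all probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none; 34741 of the first kind matched the gene table and 0 symbols changed. Probe sets with several symbols or none were left out of all gene values. The remaining ones covered 18193 genes, each represented by its probe set with the highest mean signal. The arrays' build is not given in the sources used here, so no coordinates are reported.

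Background was estimated from 80 probe sets for olfactory and vomeronasal receptors, genes mainly of sensory neurons. The 95th percentile of their signals over both arrays, log2 6.34 or a linear signal of 80.9, served as the floor. A probe set was above background on an array when its signal exceeded the floor, and lower signals were raised to the floor before the log2 ratio of HDAC9 siRNA over control siRNA was taken. A ratio with 1 signal at the floor is a bound and is given as "at least". In all, 12090 genes were above background on at least 1 array and 10732 on both.

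With 1 array per group there was no spread between samples, so no test, standard deviation between samples or p-value was computed, and the number of arrays limits the precision. Genes were counted as higher or lower at a ratio of at least 2-fold. The only internal measure of scatter came from genes with several probe sets above background: the standard deviation of the difference between the ratios of their 2 brightest probe sets, divided by the square root of 2, was 0.29 log2 over 5671 genes. This scatter includes differences between transcripts read by different probe sets and leaves out differences between cultures. A fixed set of 37 gene lists, covering deacetylases and their partners, interferon and inflammatory genes, macrophage states, metabolism, stress and markers of other cell types, was summarised by the median log2 ratio of members above background. Each median was placed among 10000 random lists of the same size drawn from 20 bins of mean signal, which describes these 2 arrays only. For the interferon-stimulated, respiratory chain and collagen genes, random lists were also matched on the genomic span of the gene in the RefSeq table (10 bins) together with mean signal (5 bins), a choice made after the data were seen. Lists with fewer than 5 members above background were given as single values.

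The groups, comparisons, lists and alternatives were chosen before the data were examined. So was the rule for named genes. It takes the class IIa deacetylases and the 12 highest and 12 lowest genes past 2-fold whose probe sets above background all had the same direction, without clone and predicted-gene names. It also takes up to 4 members of each list with the largest absolute ratios, and more where a count of 5 or fewer is listed in full; any other gene is said to have been chosen after its values were seen. The alternatives were centring on the median, quantile normalization, loess on mean signal with a span of 0.3, floors at the 75th and 99th percentiles, no floor with a pseudocount of 1, the median over a gene's probe sets, leaving out probe sets with names ending in _s_at, _x_at or _a_at, and thresholds of 1.5-fold and 3-fold. For list medians, a shift was called larger than the spread when it exceeded the standard error from 1000 bootstrap draws of the members. A planned check of RNA quality and of spike-in controls was not run, because the table analysed here held 0 control probe sets of that kind.

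The steps were tested on simulated data made from the 18193 genes of this comparison. Of 100 genes shifted by 1.5 log2 units, 92% were counted past 2-fold, as were 100% of 100 genes shifted by 2.0 units. The shifted genes were drawn only from genes with a mean signal well above the floor, so recovery of dim genes was not tested. Of 11823 unchanged genes, 0.017% were counted past 2-fold. The simulated noise was set by hand and was the same at every signal, so this share is no error rate of the real arrays. Of 200 unshifted lists, 3.0% had a median outside the 95% range of random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.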

Results

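Transcript levels were compared between peritoneal macrophages given an siRNA against HDAC9, a class IIa histone deacetylase, and macrophages given a control siRNA, 48 h after transfection. The question posed by the design was which genes differ in expression when HDAC9 is knocked down. There was 1 array per group and no replicate, so every value below describes a difference between 2 arrays that could not be set against a spread between cultures. The control array had 23158 probe sets above background (51.4%) and the HDAC9 siRNA array 24140 (53.6%). The deposited log2 signals of the arrays correlated at r = 0.947 across probe sets above background on at least 1 array; probe sets are not independent replicates. Genes above background had a median log2 ratio of 0.03, with 5th and 95th percentiles of -0.46 and 0.71.

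The siRNA target itself was close to background. Probe set 1434572_at for Hdac9 had a log2 signal of 6.88 on the control array and 5.69, below background, on the HDAC9 siRNA array, which put Hdac9 at least 1.46-fold lower. Its second probe set, 1421306_a_at, was below background on both arrays, at 5.99 and 5.94. With the floor at the 99th percentile of the receptor probe sets, Hdac9 was below background on both arrays and its ratio was 0.00. Among the 500 genes nearest to Hdac9 in mean signal after flooring, 47 (9.4%) had a ratio as low or lower, but this ranks a bound. Without a floor the deposited signals differed by -1.19. Among the 500 genes nearest in mean deposited signal, 21 (4.2%) had a difference as low or lower. Both counts were made after the data were seen, and both found other genes with differences of this size at this signal.

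The other class IIa deacetylases were not lower on the HDAC9 siRNA array. Hdac7 was 1.68-fold higher (log2 7.96 on the control array and 8.70 on the HDAC9 siRNA array), and its dimmer probe set was higher by 0.55. Hdac4 and Hdac5 had log2 ratios of 0.19 and 0.22, smaller than the 0.29 scatter of a single probe set. Of 17 histone deacetylase and sirtuin genes above background, 1 was at least 2-fold higher, the mitochondrial sirtuin Sirt4 (1.30), and the median was 0.01, at percentile 35.4 of random lists. The MEF2 transcription factors, the best known partners of class IIa deacetylases, and their corepressors had 0 of 16 genes past 2-fold. Mef2c was lower by the brightest of its 5 probe sets (log2 ratio -0.61), and Camta2, another factor bound by class IIa deacetylases, was higher (0.56). The median of that list, 0.11 at percentile 99.3, turned to -0.02 when each gene was summarised by the median over its probe sets.

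Across the transcriptome, 174 genes were at least 2-fold higher on the HDAC9 siRNA array and 45 at least 2-fold lower, together 1.81% of the genes above background. Of the 12 highest genes taken by the rule for named genes, 10 were measured above background on both arrays. They were led by Ttyh3, of a chloride channel family (5.95-fold), Kdm6b, a histone demethylase that removes a repressive methyl mark (4.35-fold, with its second probe set at 1.11 log2 units), and Col1a1, a chain of type I collagen (3.49-fold). The interferon-inducible gene Ifi213, Col4a6, Flnc, Tnk2, Slfn1, Clasrp and Cxcl10 had log2 ratios from 1.79 to 1.55. The other 2 were below background on the control array: Ddx4, a germline RNA helicase, was at least 7.23-fold higher and Tnks1bp1 at least 3.46-fold higher. Of the 12 lowest genes, 7 were measured above background on both arrays. These were Calcb, which encodes a calcitonin gene-related peptide (3.92-fold lower), Wdr48 (3.21-fold lower), Rrp9 (3.06-fold lower), the carbonyl reductase Cbr2, the pantetheinase Vnn1, Jag2 and the snoRNA host gene Snhg3, the last at -1.30. The other 5 were below background on the HDAC9 siRNA array, so their ratios are bounds without an order among them or against Calcb: Map4k1, a kinase of blood cells (at least 3.29-fold lower), the histone gene H2bc22 (at least 3.10-fold lower), Tmem151a, Melk and Maz.

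Most of these genes were dim. When genes were split into 4 equal bins by mean signal, the dimmest bin held 88 of the higher and 29 of the lower genes, and the brightest held 5 and 1. For 35 of the higher and 16 of the lower genes the ratio was a bound. A second probe set above background existed for 67 of the 219 genes, and it had the same direction in 56 (83.6%, exact 95% interval 72.5 to 91.5, counting genes, which are not replicates), against 61.2% over all 5671 genes with several probe sets. Its ratio was smaller, with a median of 0.57 against 1.14 for the brightest probe set among 57 higher genes and -0.34 against -1.12 among 10 lower genes. Without probe sets whose names end in _s_at, _x_at or _a_at, Wdr48 was at -0.13, Tnk2 at 0.19 and Flnc at 0.69. With the floor at the 99th percentile, the values of Tmem151a (-0.99), Jag2 (-0.91), Melk (-0.90) and Maz (-0.86) were bounds short of 2-fold, which leaves open whether these genes pass it. After loess on signal, 119 genes were higher and 52 lower, and 162 of the 219 genes (74.0%) were still past 2-fold in the same direction; the other 57 had a median size of 1.05 log2 units before loess and 0.94 after it.

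**Figure D1:**
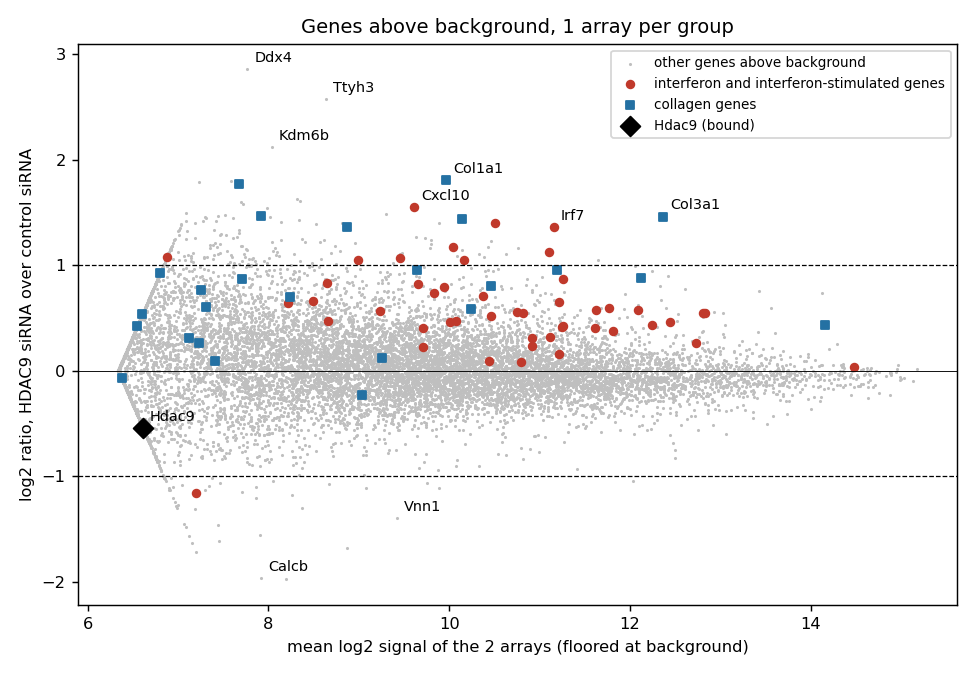
Log2 ratio of HDAC9 siRNA over control siRNA (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis), 1 point per gene above background; dashed lines mark 2-fold. Interferon-stimulated genes (red) lie above 0 in 46 of 47 cases, collagen genes (blue squares, a group chosen after its values were seen) in 23 of 25, and Hdac9 (diamond) is drawn at its bound of -0.54.

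Interferon-stimulated genes, which cells switch on in antiviral defence, were higher together on the HDAC9 siRNA array. Of 47 genes above background, 46 had a ratio above 0, and the median was 0.55 (1.46-fold), above the medians of all 10000 random lists, whose 95% range was -0.08 to 0.07. At least 2-fold higher were 9 genes, among them the chemokine gene Cxcl10 (2.93-fold), Ifit1 (log2 ratio 1.40), Irf7, the transcription factor that amplifies interferon production (2.57-fold), and Ifit3 (1.17). At least 2-fold lower was 1 gene, Ifi203, at -1.16; it belongs to a cluster of similar genes, as does Ifi213, so their probe sets are not certain to be specific to 1 gene. The interferon genes Ifnb1, Ifna4 and Ifna2 were below background on both arrays.

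**Figure D2:**
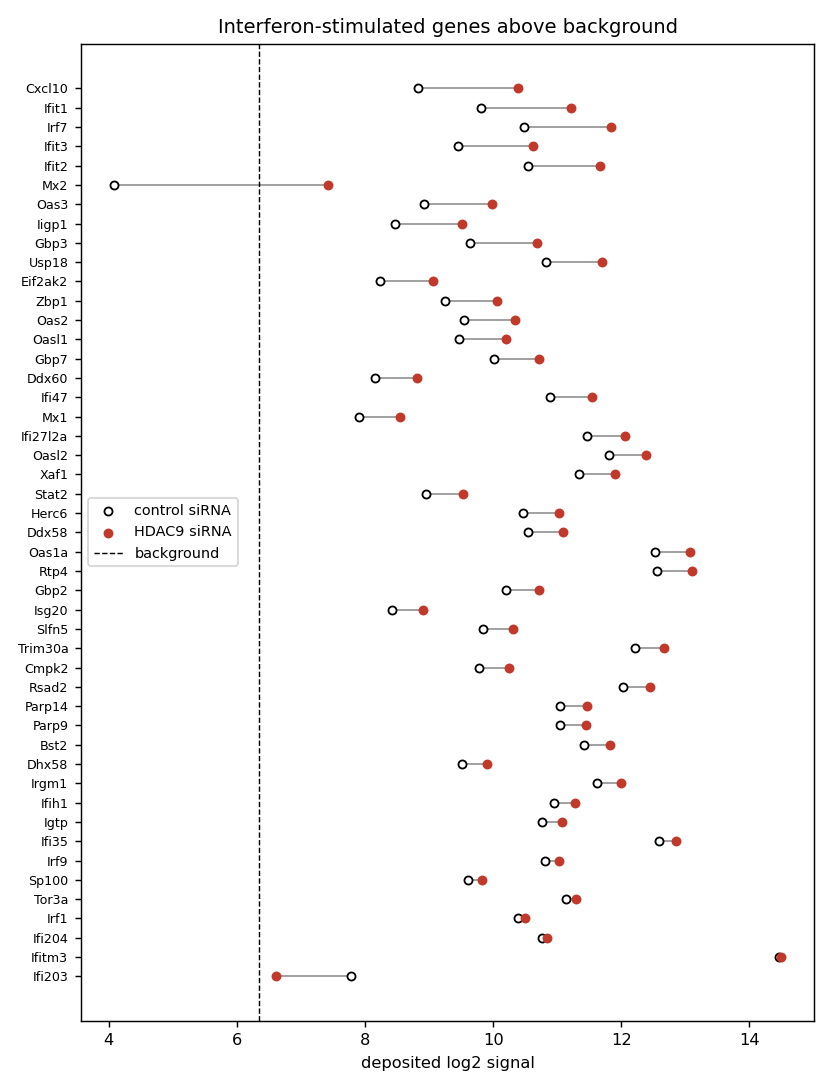
Deposited log2 signal (horizontal axis) of the 47 interferon-stimulated genes above background, 1 row per gene, on the control array (open circles) and the HDAC9 siRNA array (red circles); the dashed line is the background of 6.34. The red circle lies to the right in 46 genes and to the left in Ifi203.

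The genes that sense nucleic acids and signal toward interferon were not shifted as a group. Of 34 such genes 1, Irf7, was past 2-fold, and the median was 0.01, at percentile 60.4 of random lists. Inflammatory genes were more mixed. Of 36 inflammatory and NF-kappaB target genes, 3 were at least 2-fold higher and 0 lower: Socs3, a feedback inhibitor of cytokine signalling (1.24), Acod1, the enzyme that makes itaconate (1.16), and the cytokine gene Il6 (1.06). Their median was 0.19 (percentile 99.7). Tnf and Il1b, chosen after their values were seen as counterparts of Il6, had ratios of 0.01 and, as a bound, -0.33. Among 23 chemokine and chemokine receptor genes, some of them also on the inflammatory list, Cxcl10 and Ccl8 (1.33) were past 2-fold and Cxcl13 had the largest difference the other way (-0.82); the median was 0.17 (percentile 99.55). By the median over its probe sets Socs3 was at 0.80, and after quantile normalization Il6 was at 0.99, so neither was then past 2-fold.

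Other groups with medians above most random lists held few genes past 2-fold. None of the 15 alternative activation genes passed it, and their median was 0.25 (percentile 99.04), or 0.10 with the floor at the 99th percentile of the receptor probe sets. Fn1, which encodes fibronectin, was at 0.73 and Tgm2 at 0.58, while the lectin receptor gene Clec10a was at -0.71. Of 28 genes for extracellular matrix and proteases, 1 was higher, the proteoglycan gene Vcan (1.28, or 0.72 by the median over its probe sets), with a median of 0.09 (percentile 98.8). Of 26 immediate-early genes, 1 was higher, Egr1 (1.08), with a median of 0.12 (percentile 97.0). Of 24 genes of the p53 response and apoptosis, 1 was higher, the death receptor gene Fas (1.22), with a median of 0.09 (percentile 94.9).

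Genes of the respiratory chain and ATP synthase were lower together, by a small amount. Of 82 genes, 8 of which encode assembly factors of complex I and not subunits, 75 had a ratio below 0, and the median was -0.13, at percentile 0.01 of random lists. With random lists matched on genomic span as well, a choice made after the data were seen, it was at percentile 0.05, with a 95% range of -0.10 to -0.02. Without the assembly factors, also a later choice, 67 of 74 genes were below 0 and the median was -0.13. After loess the median was -0.10, with 15 of the 82 genes above 0. Past 2-fold was 1 gene, the complex I subunit gene Ndufs8 (-1.05), which was at -0.43 by the median over its 6 probe sets, and Atp5md followed at -0.82. Cytosolic ribosomal protein genes had a median of -0.03 (47 genes, percentile 69.9) and 1 past 2-fold, Rpl39 (1.47). Housekeeping genes had a median of -0.01 (14 genes, percentile 84.8). The medians of these last 2 lists turned positive after quantile normalization and after loess, and that of the respiratory chain stayed negative under each scaling tried.

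None of 29 macrophage core genes was past 2-fold (median -0.05, percentile 50.3, and 0.01 after loess), nor was any of 20 genes of large peritoneal macrophages (median -0.01, percentile 24.3). Of 15 genes of monocyte-derived and small peritoneal macrophages, Vcan was at least 2-fold higher and Ifitm6 lower (-1.12), while Ms4a4c was at 0.99 and the coagulation factor gene F13a1 at -0.94. The list had a median of -0.02 (percentile 52.3) that was 0.14 without probe sets ending in _s_at, _x_at or _a_at. No gene passed 2-fold among 19 for MHC class II and antigen presentation (median 0.06, percentile 78.8, and 0.17 by the median over probe sets), 25 scavenger, phagocytic and Fc receptors (0.04, percentile 96.1) and 17 complement genes (-0.01, percentile 56.6). The same held for 28 liver X receptor targets and lipid handling genes, which had a median of 0.03 (percentile 91.7). In that list the fatty acid synthesis genes Fasn and Scd1 were both at 0.80 and Pltp was at -0.59.

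Stress, proliferation and metabolic lists also had no gene past 2-fold. Their medians were -0.07 for 20 cholesterol biosynthesis genes (percentile 14.4), 0.01 for 35 cell cycle genes (percentile 29.3), 0.01 for 27 genes of the unfolded protein and integrated stress response (percentile 72.0) and 0.04 for 13 heat shock protein genes (percentile 92.5). They were -0.07 for 22 NRF2 and oxidative stress genes (percentile 21.7), -0.06 for 27 hypoxia and glycolysis genes (percentile 17.3) and -0.04 for 35 lysosome and autophagy genes (percentile 50.6, and 0.02 after loess). Of 22 DNA methylation and chromatin regulators, Kdm6b was past 2-fold, and the list's median was -0.01 (percentile 41.0).

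Markers of other cell types were measured on the same arrays. Of 17 T cell markers measured, 5 were above background, and their median was -0.72, below all random lists: Cd8a was at -0.79 (a bound), Lat at -0.77, Thy1 at -0.72, Cd28 at -0.64 and Il7r at 0.04. The T cell receptor chain genes Cd3d, Cd3e and Cd3g, chosen after their values were seen, were below background on both arrays, and with the floor at the 75th percentile the list's median was 0.0045. Of 23 mesothelial and stromal markers, Col1a1 and Col3a1 (1.46) were at least 2-fold higher. Msln was at least 2-fold lower (-1.11, or a bound of -0.57 with the floor at the 99th percentile), and Krt7 was at -0.99. Chosen after their values were seen, Krt18 (-0.44), Krt19 (-0.18) and Krt8 (-0.17) were also lower, while Lrrn4 (0.56), Wt1 (0.44) and Upk3b (0.24) were higher. The list's median of 0.13 (percentile 99.4) thus covers genes that moved in opposite directions. B cell markers had a median of 0.23 (7 genes, percentile 86.1, and -0.06 by the median over probe sets) and dendritic cell markers 0.17 (8 genes, percentile 74.9). Too few markers were above background for a median in NK cells (Prf1 at 0.07), neutrophils (Csf3r at 0.45, Mmp8 at 0.10, Mmp9 at 0.05 and S100a8 at -0.22), mast cells and basophils (Gata2 at 0.65 and Tpsab1 at 0.16 as a bound), eosinophils (Siglecf at -1.08) and erythroid cells (Hba-a2 at 0.39 and Klf1 at -0.37 as a bound).

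**Figure D3:**
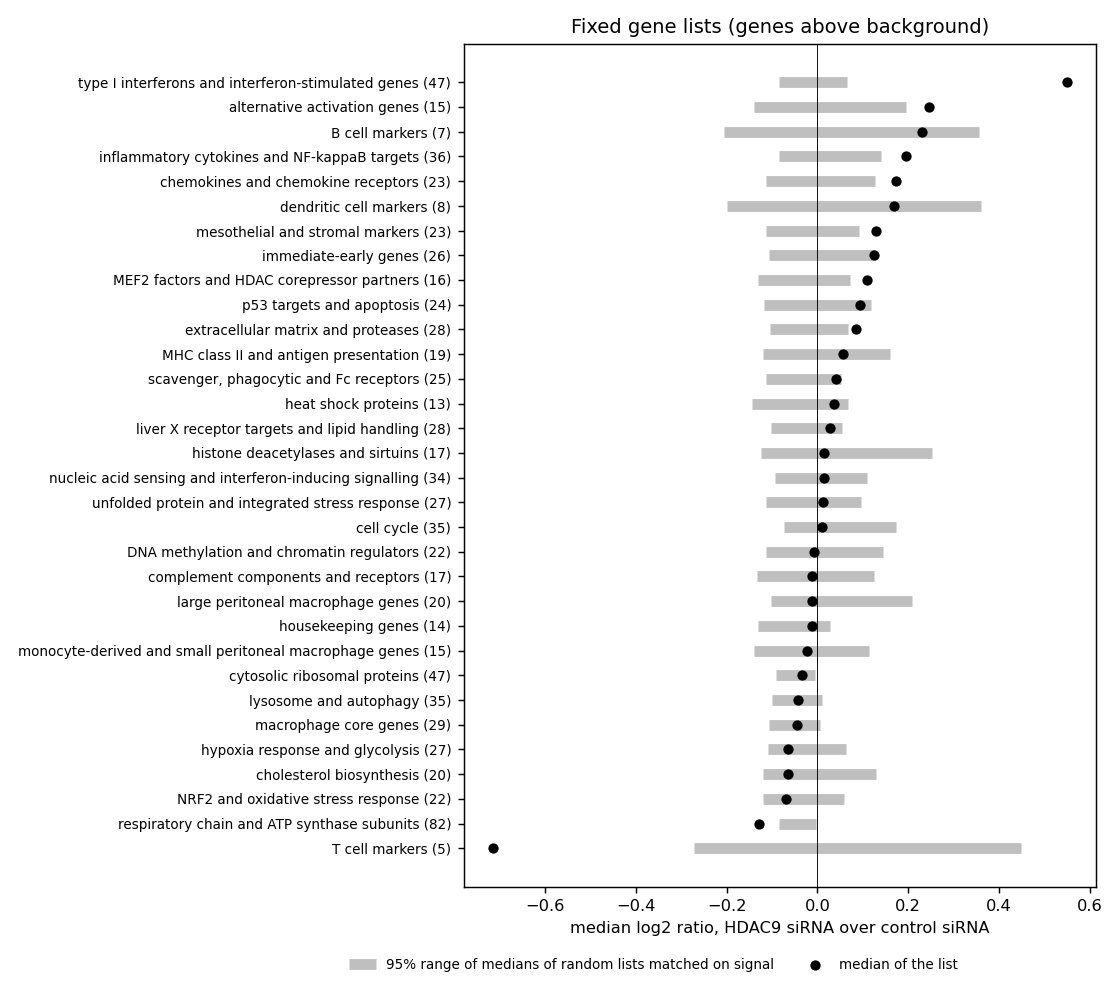
Median log2 ratio of HDAC9 siRNA over control siRNA (horizontal axis, black points) for each fixed gene list with at least 5 genes above background, with the number of genes in brackets; grey bars are the 95% range of medians of random lists matched on signal. The interferon-stimulated genes lie farthest to the right, at 0.55, and the 5 T cell markers farthest to the left, at -0.72.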

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

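Restricting counts to genes above background on both arrays and all alternatives for collagen genes were chosen after seeing the data; the others were planned. Moving the floor changed which dim genes have a ratio, so Hdac9 was at -1.19 with the floor at the 75th percentile, 0.00 at the 99th and -1.18 with no floor. Genes at least 2-fold higher and lower numbered 658 and 259 with the lower floor, 116 and 21 with the higher floor and 2223 and 1481 with none; 944 and 337 passed 1.5-fold, 10 and 6 passed 3-fold, and 139 and 29 were above background on both arrays. Of 152 named genes under 1203 alternatives, 1130 values stayed within the single-probe-set scatter, 73 moved by more and 0 genes past 2-fold changed sign. Some genes short of 2-fold did change sign. Among them were Tank (-0.77, or 0.59 without _s_at, _x_at and _a_at probe sets) and Hspa4 (0.28, or -0.40 by the median over its probe sets). Of 262 alternative list medians, 233 stayed within the bootstrap error. Centring on the median gave -0.073 for macrophage core, -0.093 for hypoxia and glycolysis, -0.071 for lysosome, -0.041 for housekeeping, -0.061 for ribosomal and -0.16 for respiratory chain genes. Quantile normalization gave -0.0049 for macrophage core, 0.00 for lysosome, 0.041 for housekeeping, 0.019 for ribosomal and -0.10 for respiratory chain genes. Loess gave 0.0055, 0.019, 0.060, 0.035 and -0.10 for these lists and -0.034 for hypoxia and glycolysis. The median over a gene's probe sets turned MEF2 factors and partners to -0.016 and gave 0.48 for interferon-stimulated genes. It gave 0.17 for the joint list of MHC class II and antigen presentation genes. For lysosome genes it gave 0.0018, for housekeeping -0.049, for ribosomal -0.048 and for B cell genes -0.064. Without _s_at, _x_at and _a_at probe sets, monocyte-derived macrophage genes were at 0.14 and ribosomal genes at -0.084. The floor at the 99th percentile gave 0.10 for alternative activation genes, and that at the 75th turned T cell markers to 0.0045. The cause of these list shifts was not tested.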

Other observations

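The collagen genes, the gene families and the stromal levels below were looked at only after the data were seen. The tests chosen only after the result was seen were those on interferon-stimulated and collagen genes, on gene span, on genes with 1 probe set, on lower genes with a second one and on the size of differences after loess. Collagen genes formed the other large group that was higher on the HDAC9 siRNA array. Of 25 collagen genes above background, 23 had a ratio above 0, 6 were at least 2-fold higher and 0 lower, and the median was 0.76, above all 10000 random lists. They included the fibrillar chains Col1a1 (1.80) and Col3a1 (log2 signal 11.6 on the control array and 13.1 on the HDAC9 siRNA array) and Col6a2 (1.44). Each of these 3 genes had 2 probe sets above background, all of them past 2-fold. Col1a2, already at 13.9 on the control array, was at 0.43.

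Genes sharing the first letters of their symbols were scanned as 140 families of at least 10 genes. Of these, 3 had medians in the lowest 0.5% of random lists and 5 in the highest 0.5%, where chance gives 0.7 on each side. C-type lectin genes, which include fungal and glycolipid receptors of macrophages, had a median of -0.29 over 16 genes, between -0.35 and -0.25 under the alternatives; Clec7a, the beta-glucan receptor gene, was at -0.36 and Clec4n at -0.40. Regulators of G protein signalling (Rgs genes) had a median of -0.23 over 13 genes, with Rgs2 at -0.43 and Rgs1 at -0.38. The third family on the lower side was that of genes starting with Atp (-0.10, 63 genes). It includes ATP synthase genes that are also on the respiratory chain list, so it is no separate observation for those genes. On the higher side, besides collagens, were Parp genes (median 0.35, 11 genes, of which Parp9 and Parp14 are also on the interferon list), the chemokine genes starting with Ccl (0.34, 13 genes), genes starting with Sh (0.28, 26 genes of mixed function) and Trim genes (0.21, 38 genes). Ratios also went weakly with genomic span (Spearman rho 0.09 across genes), from a median of -0.02 in the shortest of 10 bins to 0.12 in the longest. These bins were not matched on signal, and the median ratio fell from 0.15 in the dimmest of 4 signal bins to -0.04 in the brightest. Among random lists matched on span as well as signal, the interferon-stimulated and collagen medians were still above all 10000. The upper end of the 95% range for collagen genes was 0.25. Several stromal and mesothelial genes had signals far above background on both arrays of these macrophage preparations. Dcn was at 13.7 and 13.8 on the control and HDAC9 siRNA arrays, Sparc at 13.9 and 14.0 and the mesothelial gene Upk3b at 12.5 and 12.7.

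For the interferon-stimulated genes, a signal-dependent bias between the arrays is argued against, since after loess their median was 0.57. A larger share of macrophages is argued against, since the highest ratio among 29 macrophage core genes was 0.43, below the interferon median, while a larger share of stromal cells stays open, as the stromal median of 0.13 covers genes from -1.11 to 1.80. An interferon response to the transfected RNA itself, which siRNAs of different sequence might trigger unequally, could not be told apart from an effect of lower Hdac9. It stays open because the design has 1 siRNA of each kind, and because 0 of 3 measured type I interferon genes were above background, which at 48 h excludes neither. RNA quality and differences between cultures also stay open, the first for lack of control probe sets and the second for lack of replicates.

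For the collagen genes, signal-dependent bias is argued against by a median of 0.63 after loess. A rise of all stromal cells alike would raise their other transcripts as well. The median of 9 stromal and mesothelial genes other than collagens with a mean log2 signal of at least 11 was 0.13, with values from -0.11 to 0.24. That limit was set after the data were seen. These 9 genes argue against such a rise as the whole source. The median was 0.16 for 13 genes from 10 upward and 0.09 for all 20. The 20 include Msln (-1.11) and Krt7 (-0.99), so their median mixes genes that moved in opposite directions and does not bear on this. A rise of some stromal cells stays open, since the 4 genes between 10 and 11, Efemp1 (0.77), Lum (0.58), Lrrn4 (0.56) and Wt1 (0.44), had a median of 0.57. A change of expression within the stromal cells of the culture, or in macrophages, may underlie the shift, as a hypothesis that these 2 arrays cannot separate from RNA quality or from a difference between cultures.

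For the genes at least 2-fold apart, noise of single probe sets as the whole source is argued against where it could be tested, since 83.6% of second probe sets had the same direction. Among lower genes with a second probe set the share was 70.0% of 10, with an exact 95% interval of 34.8 to 93.3, and 152 genes had 1 probe set, so for both of these noise cannot be told apart from a difference between the samples. Loess removes only scaling and a trend shared by genes of similar signal. It took a median of 0.08 and at most 0.50 log2 units off these genes, whose median size was 1.16 before and 1.11 after it. Such a trend was too small to be the whole source of these differences, and loess says nothing on other sources. The trend bears on the count near the threshold, as 74.0% of the genes were still past 2-fold. That share is under the 80% set beforehand, so the planned test did not decide. A different share of another cell type was not settled: the T cell median of -0.72 rests on 5 of 17 markers without the Cd3 genes and could bear on the 45 lower genes at most, and for higher genes some stromal cells stay open as above. An effect of HDAC9 knockdown stays open as well and was not tested, because no replicate array shows how often such genes differ without it.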
